A study of Mus musculus with 14 samples.

How the data were processed

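Total RNA was sequenced from CD8 T cells isolated from C57BL/6 mouse spleens and sorted as naive cells, with high CD62L and low CD44. Per the labels' protocols, the cells were stimulated for 6 h with 1 µg/mL plate-bound anti-CD3 and 1 µg/mL soluble anti-CD28, with or without 20 ng/mL IFN-beta. Libraries were made from 100 ng of total RNA with a stranded total RNA kit and read as 75-base pairs on a NextSeq instrument, per the same protocols. The titles place 14 libraries in 4 groups: 3 wild-type and 3 Morrbid-/- libraries without IFN-beta, and 4 wild-type and 4 Morrbid-/- libraries with it. Nothing in the labels says whether replicates came from separate animals, so all p-values measure the spread between these samples, which may be technical.

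The authors deposited 2 tables of normalized counts, a signal that is never negative, one for each stimulation. The submitters' processing notes name Trimmomatic, STAR 2.5, featureCounts and DESeq2 and the builds GRCm38 and mm10, without roles. The annotation release, the strand setting and the filters are not given in the sources used here, so reads of overlapping, antisense and near-identical genes may be shared between them. Each deposited signal value was a whole multiple of 1 step per library, as read counts divided by one size factor per library give. Dividing by that step gave whole reads, within 0.01, for 100% of the values of each library. The tables were normalized separately, so levels with and without IFN-beta were set side by side and never tested against each other.

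The table without IFN-beta held 14732 genes, of which 222 had no symbol and 456 were at 0 in all libraries. The table with IFN-beta held 12843 genes, of which 138 had no symbol and 47 were at 0 in all libraries. Of the 15036 Entrez gene identifiers, 14359 matched the RefSeq gene table of GRCm38.p6, from which the coordinates were taken. Recovered reads per library ranged from 1747634 to 2963149 without IFN-beta and from 5788070 to 7355337 with it. Intervals on read numbers cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.88 to 9.23, so none was treated as a library deposited more than once.

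The test, the rules for named genes and the gene lists were fixed before the data were examined. Genotypes were compared within each table with limma 3.58.1 in R 4.3.3, on log2(normalized count + 1) with a mean-variance trend. Genes with a mean of at least 10 were tested, and Morrbid was kept whatever its mean. That left 9291 genes without IFN-beta and 9964 genes with it. Adjusted p-values are Benjamini-Hochberg values from limma, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and always give the Morrbid-/- label minus wild type. The difference of the genotype effect between stimulations was the interaction contrast of one limma fit of all 14 libraries, over 9078 genes with a mean of at least 10 in both tables.

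The genes named were Morrbid, Bcl2l11 and their measured neighbours, and up to 10 genes higher and 10 lower in each comparison. The latter had an adjusted p under the threshold, a mean of at least 50, no overlap between genotypes and no model name, in order of fold change. Where fewer than 5 passed in a direction, the 5 with the smallest p were named. For the difference between stimulations, the 5 genes with the smallest p in each direction were named, among those with a mean of at least 50 in both tables and no model name. In each gene list, up to 4 passing members were named, or else the 2 with the smallest p as values. The result of 1 gene that met these rules is not reported here, though it stays in all counts.

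A set of 30 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, where at least 5 members were measured. Benjamini-Hochberg adjustment ran over the lists of a comparison, and camera with an estimated correlation and fry were run beside it. The lists covered the type I interferon response, the BCL2 family, T cell signalling and differentiation, metabolism, cell cycle, stress, noncoding and mitochondrial transcripts, markers of other cell types, sex-linked genes and the genes near Morrbid. Of their members, 1 gene had no match. Shared calls between the comparisons were tested with one-sided Fisher exact tests.

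The alternatives were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, rescaling to equal totals, quantile normalization, limma without the trend, robust empirical Bayes, array quality weights, the replicate number as a block, one fit of all libraries, and leaving out each library. The quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads. By edgeR, 58 genes passed without IFN-beta, 1011 with it and 114 for the difference between stimulations. Adjusted p-values that DESeq2 gave as missing stayed missing. After the data were seen, 3 alternatives were added: removal of a GC and length trend per library, the share of mitochondrial 16S rRNA as a covariate, and thinning of reads to the shallowest library. Stretches of 75 bases shared exactly with other genes were searched in GENCODE transcripts.

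The fits were tested on simulated data with 200 changed genes. Simulated genes varied independently, with no shift shared by the genes of a library, so the real libraries may give more false calls. For the comparison without IFN-beta, over 9198 simulated genes, limma recovered 49.3% of the 1.5-fold, 81.8% of the 2-fold and 100% of the 4-fold changes, with 8 false calls. For the comparison with IFN-beta, over 9896 genes, it recovered 69.7%, 92.3% and 100%, with 10 false calls. For the difference between stimulations, over 8987 genes, it recovered 32.8%, 80% and 98.5%, with 16 false calls.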

Results

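Naive CD8 T cells from the spleen, the precursors of cytotoxic T cells, were compared between wild-type and Morrbid-/- mice after 6 h of activation in culture. Morrbid is a long noncoding RNA whose gene lies near Bcl2l11, which encodes the pro-apoptotic protein BIM. Antibodies against CD3 and CD28 stood in for antigen receptor and costimulatory signals, and IFN-beta, a type I interferon, was added in one of the settings. There were 3 libraries per genotype without IFN-beta and 4 per genotype with it. Recovered reads without IFN-beta were 2831086, 2360619 and 2963149 in wild type and 2443158, 1747634 and 2182629 in the libraries labelled Morrbid-/-. With IFN-beta they were 5788306, 6584853, 5788070 and 6918633 in wild type and 7155896, 7132515, 7279994 and 7355337 in the libraries labelled Morrbid-/-. Values below are deposited normalized counts, as mean ± SD over the libraries of a group. The 4 genes of the sex-linked list that lie on the Y chromosome were present in all libraries (Ddx3y, 476 to 507 without and 1248 to 1416 with IFN-beta). Xist, the RNA of the inactive X chromosome, was at 0 to 2.03 without IFN-beta. With IFN-beta the Y-linked genes Uty (-0.29, SE 0.07; limma adjusted p = 0.0125) and Eif2s3y (-0.28, SE 0.07; adjusted p = 0.0148) were lower in the libraries labelled Morrbid-/-.

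The Morrbid transcript was near the detection floor in every library stimulated without IFN-beta and was not lower in the libraries labelled Morrbid-/-. It is listed under its older symbol Gm14005 (chromosome 2, 128298663 to 128429351 in GRCm38.p6). The wild-type libraries held 1.79, 4.16 and 1.53 normalized counts of Morrbid, from 2, 4 and 2 reads. The libraries labelled Morrbid-/- held 7.10, 5.24 and 7.16, from 7, 4 and 7 reads. The means were 2.49 ± 1.45 and 6.5 ± 1.09 (SD, n = 3 each), a log2 difference of 1.17 (SE 0.56; limma adjusted p = 0.811). Over all libraries, 8 reads stood against 18, a rate ratio of 2.88 with a 95% counting interval of 1.19 to 7.65. These few reads did not show the loss of Morrbid that the labels give, and every direction below follows the labels. The labels do not say which part of Morrbid was deleted, and reads outside a deleted part check nothing. Morrbid in the libraries with IFN-beta was not analysed here, so their labels were not checked against it.

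Bcl2l11 (chromosome 2, 128126038 to 128162547), the neighbour of Morrbid, fell with IFN-beta in the libraries labelled Morrbid-/-. Its level there was 412 ± 58.2, against 665 ± 77.3 in wild type (SD, n = 4 each), a log2 change of -0.70 (SE 0.10; limma adjusted p = 3.14e-05). The genotypes did not overlap: the wild-type libraries held 746, 687, 668 and 561, and those labelled Morrbid-/- held 482, 420, 404 and 340. Without IFN-beta, Bcl2l11 was at 386, 322 and 459 in wild type and at 320, 269 and 311 in the libraries labelled Morrbid-/-. These means, 389 ± 68.6 and 300 ± 27.7 (SD, n = 3 each), differed by -0.36 (SE 0.12), which did not pass (adjusted p = 0.424). The difference did pass with the mitochondrial 16S rRNA share as a covariate (adjusted p = 0.0494) and with the replicate number as a block. The genotype effect on Bcl2l11 did not differ detectably between stimulations (difference -0.33, SE 0.17; adjusted p = 0.44). Of the other measured neighbours, Tmem87b alone passed, with IFN-beta, at 473 ± 10.5 against 558 ± 36.3 (-0.24, SE 0.07; adjusted p = 0.0398). The tested neighbours without IFN-beta, 11 genes with Morrbid and Bcl2l11 among them, gave 0 higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.532, with a downward direction against a median of 0.03). The 10 tested with IFN-beta gave 0 higher, 2 lower and 8 not called (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.609). Among those not called with IFN-beta were Slc20a1 (0.20, adjusted p = 0.0801), Zc3h6 (0.19, adjusted p = 0.112) and Acoxl (-0.83, adjusted p = 0.201). Slc20a1 passed after rescaling to equal totals (limma adjusted p = 0.0324), with the replicate number as a block (0.0495) and with the GC and length trend removed (0.0422). The call on Tmem87b was lost when any of 7 single libraries was left out, with an adjusted p of 0.108 without Morrbid-/- replicate 2, and Acoxl passed without wild-type replicate 3 (adjusted p = 0.0219).

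**Figure D1:**
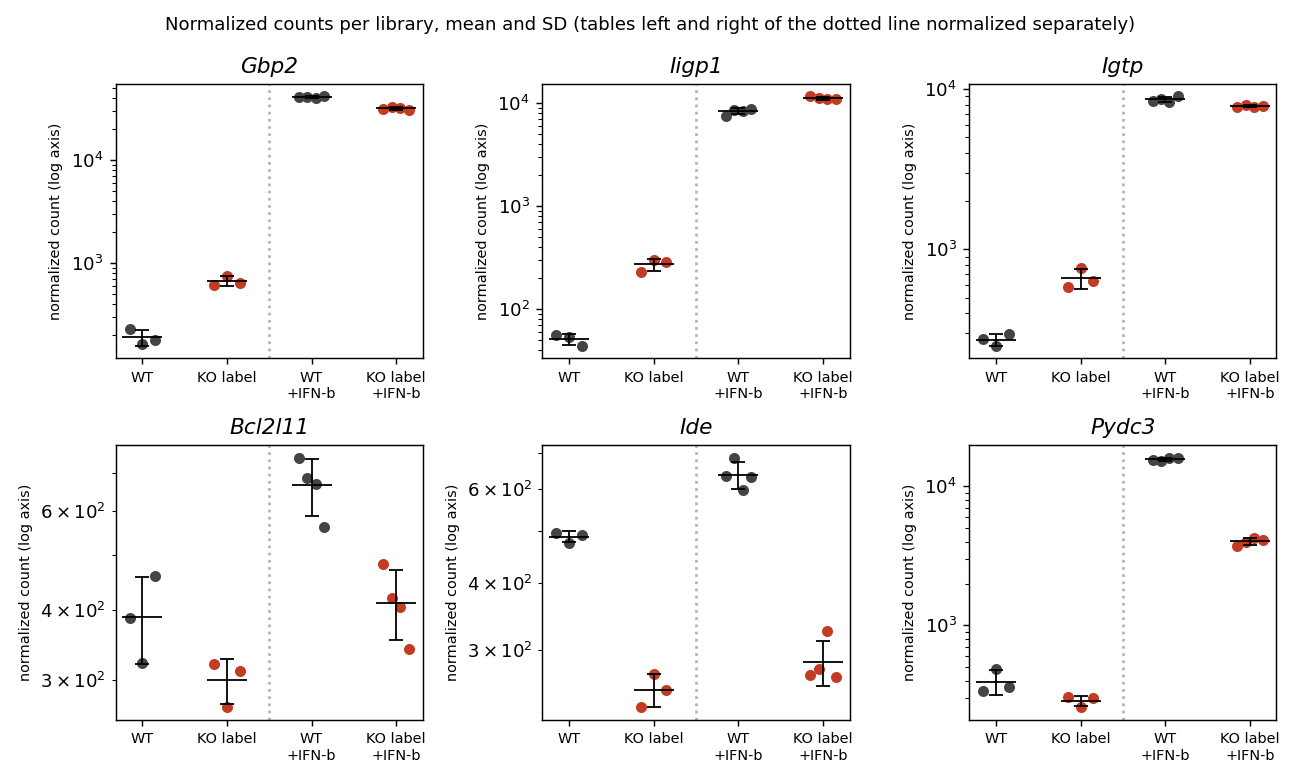
Normalized counts of Gbp2, Iigp1, Igtp, Bcl2l11, Ide and Pydc3 per library on log axes, with the mean and SD of each group, 3 libraries per genotype without IFN-beta and 4 with it, KO label standing for the Morrbid-/- label. Gbp2 rose from 190 to 667 between genotypes without IFN-beta, and Ide was lower in the libraries labelled Morrbid-/- in both tables, which were normalized separately.

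In cells activated without IFN-beta, interferon-response genes were higher in the libraries labelled Morrbid-/-. Iigp1 and Igtp, interferon-inducible GTPases of cell-autonomous defence, rose from 51.6 ± 6.38 to 275 ± 36.4 and from 273 ± 22.7 to 658 ± 91.3 (SD, n = 3 each). The guanylate-binding protein gene Gbp2 rose from 190 ± 33.4 to 667 ± 74.2. In log2 terms these were changes of 2.39 (SE 0.15; limma adjusted p = 1.91e-10) for Iigp1, 1.26 (SE 0.11; adjusted p = 9.6e-08) for Igtp and 1.81 (SE 0.12; adjusted p = 6.18e-10) for Gbp2. Gbp6 (1.66), Gbp5 (1.59), Ifit1 (1.36), Gvin1 (1.32), Tgtp1 (1.20) and Gbp4 (1.18) also rose, with adjusted p-values between 3.82e-07 and 1.69e-04. Most of these belong to multigene families, and exact shared stretches of 75 bases were searched for Iigp1 but not for the others. Fewer genes fell. Erdr1, whose gene lies near the end of the X chromosome, fell from 384 ± 100 to 86.6 ± 23.8 (-2.13, SE 0.18; adjusted p = 4.16e-08), and 35% of its 75-base stretches occurred in another gene. Ide, the insulin-degrading enzyme, fell from 488 ± 11.5 to 252 ± 17.8 (-0.95, SE 0.10; adjusted p = 1.49e-06). Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 1.05 (SE 0.19; adjusted p = 0.00228). The chemokine receptor gene Ccr9 (-0.86, SE 0.19; adjusted p = 0.0265) and Yae1d1 (-0.76, SE 0.17; adjusted p = 0.0286) were the other named genes that fell. Yae1d1 did not pass when any of 5 single libraries was left out (adjusted p = 0.207 without wild-type replicate 1), Ccr9 when any of 3 was (0.489 without wild-type replicate 2), and Lars2 without wild-type replicate 2 (0.0546). No overlap between genotypes was part of the rule that named these 14 genes, so it adds nothing to their calls.

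In all, 50 genes were higher and 9 lower of 9291 tested, and 569 had an unadjusted p under 0.05. Of those that passed, 32 higher and 5 lower genes changed over 2-fold. The genotypes did not overlap in 1016 genes, or 10.9%, where chance gives 10%. Without the Morrbid-/- replicate 2 the higher genes numbered 31, and the lower genes numbered 20 without wild-type replicate 3 and 23 without Morrbid-/- replicate 1. Without limma's mean-variance trend 13 were higher and 4 lower.

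The tested genes of the type I interferon response list rose as a group without IFN-beta. Of its 56 genes 41 were tested, with 16 higher, 0 lower and 25 not called (28 higher and 0 lower adjusted over the list alone). The untested genes were too low or absent. Of those present, Isg15 (1.40 in wild type, 1.36 in the libraries labelled Morrbid-/-), Isg20 and Mx2 were lower with that label. The others, such as Cmpk2 (1.46 and 5.39), were higher, all at low levels. The median change of the tested genes was 0.54 (camera adjusted p = 1.86e-51, but adjusted p = 0.0619 with an estimated correlation). No list of genes that respond to another interferon was tested, so the type of interferon was not told apart. Ifit3 (2.30, adjusted p = 7.01e-05) and Usp18 (1.34, adjusted p = 0.0283), an inhibitor of interferon receptor signalling, passed beside Gbp2 and Ifit1. The share of reads from mitochondrial 16S rRNA separated these libraries in another way than genotype. It was 18.1%, 16% and 12.5% in wild type and 18.9%, 12.8% and 11.6% in the libraries labelled Morrbid-/-. The interferon list's median was 0.46 within the 3 libraries of high share (2 wild type, 1 Morrbid-/-) and 0.81 within the 3 of low share (1 wild type, 2 Morrbid-/-). The median of 81 ribosomal protein genes was -0.19 between genotypes, with 0 higher and 0 lower, and -0.36 between the libraries of low and high 16S share, with 0 higher and 35 lower.

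Genes of T cell activation and effector function also moved up as lists without IFN-beta, with few single genes passing. The cytotoxic effector list had 2 genes higher, 0 lower and 12 not called of 14 (5 higher adjusted over the list alone; camera adjusted p = 7.43e-07, adjusted p = 0.106 with an estimated correlation). These were Il12rb2, a chain of the interleukin-12 receptor, at 15.4 ± 8.98 against 55.0 ± 1.28 (1.98, SE 0.35; adjusted p = 0.00174), and the transcription factor gene Eomes (0.84, SE 0.18; adjusted p = 0.0223). The list of T cell receptor early activation had 0 higher and 0 lower of 32 (1 higher adjusted over the list alone; camera adjusted p = 1.06e-07, adjusted p = 0.28 with an estimated correlation). Its members Irf8 and Myc were at 1.08 (adjusted p = 0.0903) and 0.41 (adjusted p = 0.305). NF-kB targets had 0 higher and 0 lower of 20, also over the list alone (camera adjusted p = 8.18e-06, adjusted p = 0.268 with an estimated correlation), with Icam1 at 0.39 (adjusted p = 0.482) and Rel at 0.26 (adjusted p = 0.605). Coinhibitory receptors had 1 higher of 9, Cd274, the gene for PD-L1 (0.86, SE 0.13; adjusted p = 2.35e-04), and 2 higher adjusted over the list alone (camera adjusted p = 0.00287, adjusted p = 0.274 with an estimated correlation). Cytokine-STAT feedback genes had 2 higher, 0 lower and 23 not called, Il12rb2 and the kinase gene Pim2 (0.77, adjusted p = 0.00228), also over the list alone (camera adjusted p = 0.0213, adjusted p = 0.334 with an estimated correlation).

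The lists of naive-cell and identity genes moved down without IFN-beta, again with no single gene passing. The naive and FOXO1-associated list had 0 higher and 0 lower of 24 (camera adjusted p = 0.00186, adjusted p = 0.397 with an estimated correlation), with S1pr1, a lymphocyte egress receptor gene, at -0.31 (adjusted p = 0.385) and Cdkn1b at -0.31 (adjusted p = 0.547). CD8 T cell identity genes had 0 higher and 0 lower of 21 (camera adjusted p = 0.0193, adjusted p = 0.397 with an estimated correlation), with Cd3d at -0.40 (adjusted p = 0.378) and Thy1 at -0.30 (adjusted p = 0.581). Glycolysis and nutrient transport moved up with 0 higher and 0 lower of 22 (camera adjusted p = 0.0104, adjusted p = 0.456 with an estimated correlation), with Slc7a5 at 0.27 (adjusted p = 0.811). Markers of CD4 and regulatory T cells moved up with 0 higher and 0 lower of 7 (camera adjusted p = 0.0193, adjusted p = 0.28 with an estimated correlation), with Ctla4 at 0.47 (adjusted p = 0.621) and Ikzf2 at 0.41 (adjusted p = 0.67). Calls on these 4 lists were lost without wild-type replicate 2, with an adjusted p of 0.137 for the naive list, 0.0691 for CD8 identity, 0.347 for glycolysis and 0.137 for CD4 and regulatory markers. Other single libraries also ended the last 3 of these calls, and the cytokine-STAT call was lost without wild-type replicate 1 (adjusted p = 0.133) or Morrbid-/- replicate 2 (adjusted p = 0.0876). In all, 10 of 22 tested lists passed with the preset correlation and 0 with an estimated one, and 4 passed by fry, 3 of them among the 10.

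The BCL2 family had 0 higher and 0 lower of 21 without IFN-beta (camera adjusted p = 0.853), with Bmf, a pro-apoptotic member, at -0.80 (adjusted p = 0.78). The PI3K-AKT-mTOR list had 0 higher and 0 lower of 28 (camera adjusted p = 0.826), with Pik3r1 at -0.36 (adjusted p = 0.302). Memory-phenotype CD8 markers had 2 higher and 0 lower of 13 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0637, fry adjusted p = 0.0426). These were Eomes and Ly6a, the gene for Sca-1, at 2.29 ± 2.53 against 25 ± 1.01 (3.24, SE 0.49; adjusted p = 2.43e-04). Mitochondrially encoded transcripts also did not pass (0 higher, 0 lower of 10; camera adjusted p = 0.0637), with ND6 at -0.24 (adjusted p = 0.813). Lists of ribosome biogenesis (26 genes), G1/S (18) and G2/M cell cycle (6), p53 targets (16), unfolded protein and integrated stress response (17), heat shock (10) and nuclear noncoding RNA (12) each had 0 higher and 0 lower, also over the list alone. Their camera adjusted p-values were 0.365, 0.532, 0.145, 0.145, 0.428, 0.584 and 0.826.

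**Figure D2:**
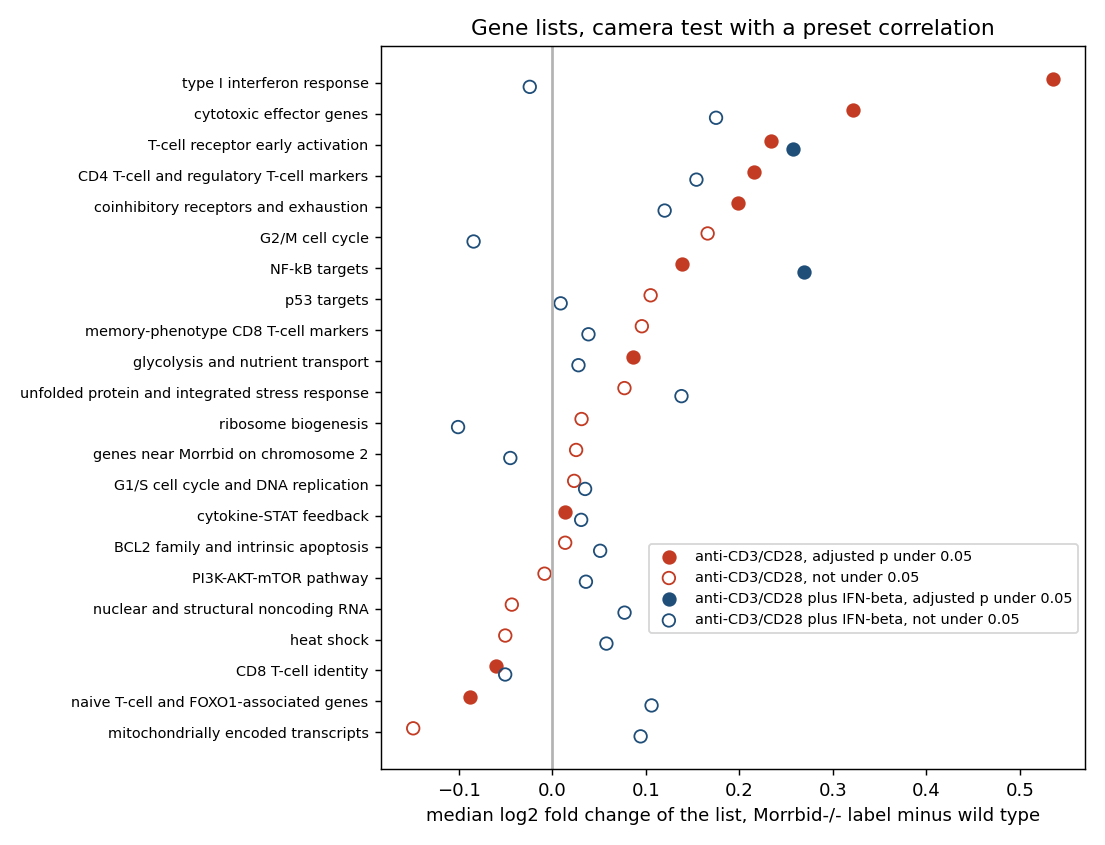
Median log2 fold change of each gene list between genotypes, the Morrbid-/- label minus wild type, without and with IFN-beta, with filled points for lists that passed camera with a preset correlation. The type I interferon response had the highest median without IFN-beta, at 0.54, and -0.02 with it.

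With IFN-beta present, many genes differed between genotypes by small amounts, and the interferon-response genes went both ways. Casz1, a zinc-finger transcription factor gene, rose from 239 ± 26.6 to 495 ± 36.2 (SD, n = 4 each; 1.05, SE 0.09; limma adjusted p = 5.25e-08). Rhob, a small GTPase gene, rose from 33.0 ± 8.70 to 82.4 ± 4.41 (1.32, SE 0.18; adjusted p = 2.64e-05), and Bhlhe40, a transcription factor gene induced by activation, from 38.6 ± 10.9 to 93.9 ± 21.3 (1.28, SE 0.20; adjusted p = 1.18e-04). Pydc3, a pyrin-domain gene of an interferon-inducible cluster, fell from 15638 ± 405 to 4022 ± 218 (-1.96, SE 0.05; adjusted p = 1.76e-18). Ide fell again, from 636 ± 37.3 to 285 ± 27.5 (-1.16, SE 0.08; adjusted p = 1.63e-09), and Cxcr6, a chemokine receptor gene, fell from 149 ± 15.8 to 79.3 ± 7.42 (-0.90, SE 0.13; adjusted p = 3.76e-05). Erdr1 was at 99.2 ± 40.6 in wild type and near the floor, with 1, 0, 1 and 4 reads, in the libraries labelled Morrbid-/- (adjusted p = 1.99e-09). Tmem181b-ps (1.14), Marcksl1 (1.14), Cdk5rap1 (1.10), Ptms (1.05), Ly6c2 (1.01), Nnt (1.00) and Fam129a (0.96) were the other named genes that rose. Rell1 (-1.91), Mcoln2 (-1.59), Gpr34 (-1.31), Ctla2a (-1.19), Abcg3 (-1.07) and Ppic (-0.94) were the others that fell. Adjusted p-values of these 13 genes ran from 6.18e-07 to 6.77e-04. The rule that named these 20 genes required no overlap between genotypes, so that too adds nothing to their calls.

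In all, 523 genes were higher and 482 lower of 9964 tested with IFN-beta, and 2434 had an unadjusted p under 0.05. The median absolute change of the 1005 genes was 0.37, and 31 higher and 21 lower genes changed over 2-fold. The genotypes did not overlap in 1512 genes, or 15.2%, where chance gives 2.86%. After rescaling to equal totals 730 were higher and 344 lower, so that 68% of the calls were higher instead of 52%. Without the Morrbid-/- replicate 2 the counts were 321 and 288, and without limma's mean-variance trend they were 171 and 134.

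NF-kB targets rose as a group with IFN-beta, with 11 of 20 genes higher, 2 lower and 7 not called (12 higher and 2 lower adjusted over the list alone). The camera test passed with both correlations (adjusted p = 4.31e-08, and adjusted p = 0.0177 with an estimated correlation). Rela, a subunit of NF-kB, rose from 349 ± 37.1 to 554 ± 31.7 (0.67, SE 0.08; limma adjusted p = 1.04e-05), Tnfaip3, its feedback inhibitor, by 0.55 (adjusted p = 3.36e-06) and the adhesion molecule gene Icam1 by 0.49 (adjusted p = 2.8e-05). Tnfaip8 fell by 0.45 (adjusted p = 0.0267). Genes of T cell receptor early activation had 8 higher, 0 lower and 24 not called of 32 (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00357, adjusted p = 0.936 with an estimated correlation). Fosb, an AP-1 subunit gene, rose from 14.7 ± 10.6 to 41.7 ± 14 (1.78, SE 0.43; adjusted p = 0.00882), and Cd83 (0.66, adjusted p = 0.00606) and Junb (0.50, adjusted p = 0.00109) rose with Bhlhe40. The camera call on this list was lost without Morrbid-/- replicate 1 (adjusted p = 0.114) or replicate 2 (adjusted p = 0.101). In all, 2 of 24 tested lists passed with the preset correlation, 1 with an estimated one and 4 by fry.

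The type I interferon response list had 10 higher, 9 lower and 36 not called of 55 genes with IFN-beta (13 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.841). Ifi44 rose from 439 ± 54.1 to 808 ± 104 (0.88, SE 0.09; limma adjusted p = 1.3e-06) and Isg15, a ubiquitin-like modifier gene, from 158 ± 13.4 to 246 ± 27.9 (0.64, SE 0.11; adjusted p = 2.72e-04). Ifit1 fell from 27549 ± 1806 to 21232 ± 1752 (-0.38, SE 0.06; adjusted p = 2.01e-04) and Gbp2 from 41222 ± 701 to 31903 ± 780 (-0.37, SE 0.05; adjusted p = 2.8e-05). In the BCL2 family 1 gene was higher, 3 lower and 17 not called of 21 (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.895, with a downward direction against a median of 0.05). Beside Bcl2l11, the anti-apoptotic Bcl2 fell from 838 ± 108 to 549 ± 37.0 (-0.60, SE 0.08; adjusted p = 2.8e-05) and Casp8 by 0.31 (adjusted p = 1.97e-04), while the death receptor gene Fas rose by 0.28 (adjusted p = 0.0269). The PI3K-AKT-mTOR list had 1 higher and 1 lower of 29, also over the list alone (camera adjusted p = 0.895), Irs2 (0.45, adjusted p = 0.0229) and Pik3cd (-0.19, adjusted p = 0.0232).

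Naive-cell genes had 8 higher, 1 lower and 16 not called of 25 with IFN-beta (8 higher and 4 lower adjusted over the list alone), but the list did not pass (camera adjusted p = 0.124). The transcription factor genes Lef1 (0.52, limma adjusted p = 7.59e-05) and Tcf7 (0.41, adjusted p = 1.05e-04), the homing receptor gene Ccr7 (0.51, adjusted p = 1.68e-04) and Sesn3 (0.36, adjusted p = 0.00215) rose. Memory-phenotype markers had 3 higher and 3 lower of 15 (4 and 4 over the list alone; camera adjusted p = 0.912), with Ly6c2, Cd44 (0.89, adjusted p = 0.04) and Ly6a (0.71, adjusted p = 1.39e-06) higher and Il18r1 (-0.55, adjusted p = 5.02e-06) lower. Coinhibitory receptors had 2 higher and 1 lower of 10, also over the list alone (camera adjusted p = 0.893), with Ctla4 (0.93, adjusted p = 7.98e-05) and Lag3 (0.85, adjusted p = 0.0177) higher and Nt5e (-0.32, adjusted p = 0.00299) lower. CD8 T cell identity genes had 0 higher and 2 lower of 21, also over the list alone (camera adjusted p = 0.128, fry adjusted p = 0.025), Themis (-0.47, adjusted p = 1.78e-04) and Trbc1 (-0.30, adjusted p = 0.0138). Cytokine-STAT feedback genes had 2 higher and 2 lower of 28, also over the list alone (camera adjusted p = 0.841), with the kinase gene Jak2 highest (0.55, adjusted p = 9.93e-07). Cytotoxic effector genes had 1 higher and 1 lower of 18 (4 and 1 over the list alone; camera adjusted p = 0.36), Id2 (0.45, adjusted p = 0.017) and Tnfsf10 (-0.24, adjusted p = 0.0137).

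Metabolic and stress lists held few passing genes with IFN-beta, and none of these lists passed camera. Glycolysis and nutrient transport had 1 higher and 1 lower of 22 (camera adjusted p = 0.912), Odc1 (0.76, limma adjusted p = 5.17e-07) and Ldha (-0.27, adjusted p = 0.0397). Ribosome biogenesis had 0 higher and 3 lower of 26 (camera adjusted p = 0.236), Wdr12 (-0.41), Heatr1 (-0.29) and Npm1 (-0.26). G1/S genes had 1 higher and 1 lower of 18 (camera adjusted p = 0.895), Mcm4 (0.30) and Mcm6 (-0.25), and G2/M genes 0 and 0 of 10 (camera adjusted p = 0.893). The p53 list had 1 higher and 1 lower of 16 (camera adjusted p = 0.912), Fas and Trp53inp1 (-0.23), and the unfolded protein and integrated stress response list 2 higher and 0 lower of 17 (camera adjusted p = 0.236, fry adjusted p = 0.0226), Ppp1r15a (0.60) and Atf4 (0.28). Heat shock genes had 1 higher and 1 lower of 12 (camera adjusted p = 0.609), Hsp90ab1 (0.42) and Chordc1 (-0.34). For these 7 lists the counts were the same adjusted over the list alone. Nuclear noncoding RNA had 1 higher and 0 lower of 12 (1 and 1 over the list alone; camera adjusted p = 0.609), Rmrp (0.59). Mitochondrially encoded transcripts had 2 higher and 2 lower of 11 (4 and 2 over the list alone; camera adjusted p = 0.895). Their median was 0.09 and their mean -0.25, and camera pointed up and fry down (adjusted p = 0.0328), with Rnr1 (0.81) and ND5 (0.34) higher and COX1 (-0.25) and ND3 lower. ND3 was at 22.8 ± 2.95, from 84 reads, in wild type and at 0 reads in the libraries labelled Morrbid-/-, so it was at least 33.4-fold lower with 3 reads allowed over the group.

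The difference between the genotype effects tested whether the effect of the Morrbid-/- label differed between the libraries with and without IFN-beta. These were separate sets of libraries, normalized separately and read to unlike depths. IFN-beta therefore cannot be told apart here from other differences between the sets. Among genes with a mean of at least 50 in both tables and no model name, the 5 negative differences with the smallest p were those of interferon-inducible GTPase genes. Each of these was higher in the libraries labelled Morrbid-/- without IFN-beta. The difference was -2.18 for Gbp2 (SE 0.13; limma adjusted p = 1.79e-11), -1.97 for Iigp1 (SE 0.13; adjusted p = 9.27e-11), -1.83 for Gbp6 (SE 0.14; adjusted p = 4.45e-09), -1.47 for Gbp7 (SE 0.11; adjusted p = 3.81e-09) and -1.40 for Igtp (SE 0.11; adjusted p = 5.69e-09). It was positive for Bcl9l, a cofactor of Wnt signalling (1.03, SE 0.16; adjusted p = 2.75e-04), Akap2 (0.87, SE 0.13; adjusted p = 1.62e-04), Kdm2b, a histone demethylase gene (0.71, SE 0.12; adjusted p = 6.11e-04), B4galnt1 (0.63, SE 0.10; adjusted p = 3.75e-04) and Chd4, a chromatin remodeller gene (0.61, SE 0.10; adjusted p = 7.61e-04). In all, 40 genes had a positive and 81 a negative difference of 9078 tested, and 1090 had an unadjusted p under 0.05. Without wild-type replicate 1 with IFN-beta the positive count was 24. Without limma's mean-variance trend the counts were 15 and 51.

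The type I interferon response list had a lower genotype effect with IFN-beta than without it, with 0 genes higher, 21 lower and 20 not called of 41 (0 and 31 adjusted over the list alone). Its median difference was -0.56 (camera adjusted p = 4.83e-50, and adjusted p = 0.00111 with an estimated correlation), led by Ifit3 (-2.23, limma adjusted p = 1.07e-08). Naive-cell genes had the opposite sign, with 3 higher, 0 lower and 21 not called of 24 (8 and 1 over the list alone; camera adjusted p = 3.01e-05, adjusted p = 0.285 with an estimated correlation). These were Cdkn1b (0.64, adjusted p = 0.042), Lef1 (0.60, adjusted p = 0.01) and Tcf7 (0.52, adjusted p = 0.0102). Memory-phenotype markers had 0 higher, 1 lower and 12 not called, Ly6a (-2.54, adjusted p = 5.66e-05), and 3 lower over the list alone (camera adjusted p = 0.0154, adjusted p = 0.0929 with an estimated correlation). Mitochondrially encoded transcripts had 0 higher and 0 lower of 10 (1 higher over the list alone; camera adjusted p = 0.0325, adjusted p = 0.722 with an estimated correlation), and that call was lost when any of 6 single libraries was left out. NF-kB targets (camera adjusted p = 0.275) and T cell receptor early activation (camera adjusted p = 0.853) did not differ detectably, with 0 higher and 0 lower in each. The BCL2 family had 0 higher and 1 lower of 20, Casp8 (-0.44, adjusted p = 0.0125; camera adjusted p = 0.436). Cytotoxic effector genes had 0 higher and 1 lower of 13, Il12rb2 (-2.01, adjusted p = 0.00106; 3 lower over the list alone; camera adjusted p = 0.418), with a median of 0.12 and a mean of -0.17. Coinhibitory receptors had 1 lower, Cd274 (-1.01; camera adjusted p = 0.128), cytokine-STAT feedback genes 2 lower, Il12rb2 and Pim2 (-0.58; camera adjusted p = 0.363), CD4 and regulatory T cell markers 1 lower, Tnfsf8 (-0.79; camera adjusted p = 0.436), and glycolysis 1 higher, Odc1 (0.56; camera adjusted p = 0.363). The PI3K-AKT-mTOR, ribosome biogenesis, G1/S, p53, stress response, heat shock, noncoding RNA, CD8 identity and Morrbid-neighbour lists had 0 higher and 0 lower, with camera adjusted p-values of 0.853, 0.122, 0.793, 0.436, 0.572, 0.436, 0.436, 0.853 and 0.853. In all, 4 of 21 lists passed with the preset correlation, 1 with an estimated one and 2 by fry.

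The genes that passed in both genotype comparisons fell into opposing and shared sets. Of the 50 genes higher without IFN-beta, 14 were lower with it, where 2.54 were expected (one-sided Fisher exact test, p = 1.08e-07, adjusted p = 4.32e-07). These were Gbp2, Gbp4, Gbp6, Gbp7, Gbp8, Tgtp1, Tgtp2, Ifi47, Ifit1, Irf1, Irgm2, Nlrc5, Gm12250 and Gm8995, of which Gbp2, Gbp7, Ifi47 and Ifit1 were in the type I interferon response list. Another 6, Gm4070, Ly6a, Tmem181b-ps, Iigp1, Gbp10 and Ms4a4c, were higher in both, where 2.69 were expected (Fisher exact p = 0.0502, adjusted p = 0.0669). Of the 9 genes lower without IFN-beta, 6 were lower with it, where 0.457 were expected (Fisher exact p = 1.22e-06, adjusted p = 2.44e-06), and 0 were higher (p = 1, adjusted p = 1). These were Ide, Erdr1, Rell1, Mid1, Synj2 and Gm14085. Synj2 was at -2.09 without and -2.23 with IFN-beta, and Mid1 at -1.76 and -1.3. Across the 9078 genes, which are not independent replicates, fold changes of the comparisons had a Pearson r of 0.168 and a Spearman rho of 0.124. The Fisher tests also count genes as independent, which genes regulated together are not, so their p-values overstate the evidence. Shared stretches were not searched for the 14 genes that changed in opposite directions.

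**Figure D3:**
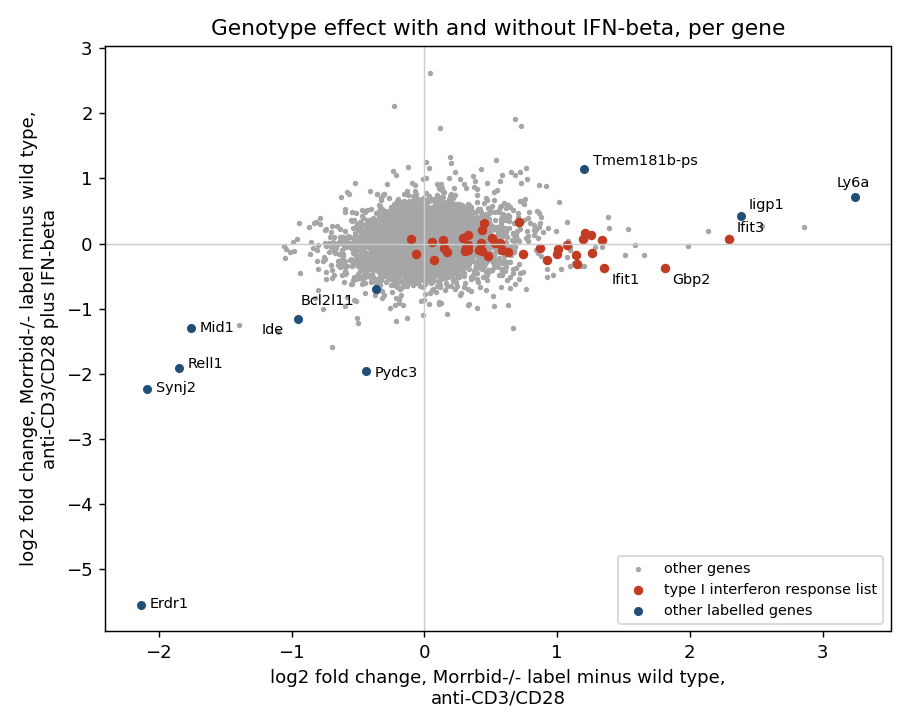
Log2 fold change between genotypes, the Morrbid-/- label minus wild type, without IFN-beta (x axis) and with IFN-beta (y axis), one point per gene tested in both. The type I interferon response list has a median of 0.54 on the x axis, with 39 of 41 genes above 0, and Ide, Rell1, Mid1, Synj2 and Erdr1 lie below 0 on both axes.

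Levels of interferon-response genes were far apart between the tables, which were normalized separately and not tested against each other. In wild type, Ifit1 stood at 36.5 ± 10.3 without IFN-beta and at 27549 ± 1806 with it. Gbp2 stood at 190 ± 33.4 and 41222 ± 701, Iigp1 at 51.6 ± 6.38 and 8315 ± 556, and Usp18 at 10.8 ± 2.15 and 7377 ± 294 (SD, n = 3 without and n = 4 with IFN-beta). In the libraries labelled Morrbid-/- without IFN-beta these genes stood at 93.1 ± 7.94 (Ifit1), 667 ± 74.2 (Gbp2), 275 ± 36.4 (Iigp1) and 28.6 ± 0.216 (Usp18), all far below the wild-type levels with IFN-beta.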

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

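The tests of exchanged labels, of shared stretches and of neighbouring gene pairs were chosen after the results they bear on had been seen. The test of exchanged labels was set first on the edgeR result for Morrbid, whose unadjusted value of 0.0238 (edgeR adjusted p = 0.734) would have met it, and was replaced after that value was seen by a limit of 3 reads in a group. The test of shared stretches was a single one, met by 8 of the 11 searched genes, before it was split into genes with and without such a stretch. The test on other cell types was renamed after its value of 0.216 was seen, with its bounds unchanged, and the test on B cells, myeloid cells and neutrophils was added then, before its own value was seen.

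Interferon-response genes were higher without IFN-beta in the libraries labelled Morrbid-/-, with a list median of 0.54 (SE 0.10). Scaling of the libraries was argued against by a lowest median of 0.542 under other scalings, and the mitochondrial 16S rRNA split by a median of 0.559 with its share as a covariate. RNA from B cells, myeloid cells or neutrophils was argued against by their 8 abundant markers, whose sum changed by -2.07 (SE 3.84) normalized counts and so did not rise. RNA from CD4, regulatory or memory-phenotype T cells, which the sort for naive CD8 cells was meant to remove, could not be told apart from a genotype effect, since among the 3 types with at least 3 tested markers the highest median was 0.216 (SE 0.15), 1.76 standard errors below that of the list. A genotype effect on interferon signalling and an earlier interferon exposure of the mice both may remain, and neither was tested here. Strain or donor variants were not tested for the interferon list either. An arbitrary grouping of these libraries was not settled, since 2 of 10 splits called at least as many genes as the labels, the labels included.

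Bcl2l11 fell with IFN-beta in the libraries labelled Morrbid-/-, and Morrbid reads did not fall without it, although Morrbid is known as a repressor of Bcl2l11. A difference in library depth was argued against by the change of Bcl2l11, which stayed at -0.656 after reads were thinned to the shallowest library. Exchanged genotype labels could not be told apart from correct ones, since the libraries labelled wild type held 8 Morrbid reads, over the limit of 3, and those labelled Morrbid-/- held 18. A deletion that leaves part of Morrbid transcribed may give the same reads, and was not tested here.

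The 12 genes changed the same way with and without IFN-beta, among them Ide, Erdr1, Mid1, Synj2 and Rell1, were weighed against 3 explanations. DNA linked to Morrbid on chromosome 2 was argued against as the whole cause, since 1 gene of the set, Gm14085, lay within 20 Mb of Morrbid. Reads shared through exact copies of 75 bases in annotated transcripts were argued against for the 3 genes with no such stretch, Ide, Iigp1 and Rell1. Another 8 genes had one, in 96.7% of the stretches of Gm4070, 77.8% of Gbp10, 35% of Erdr1, 21.6% of Gm14085, 13.6% of Mid1, 6.33% of Ly6a, 3.78% of Ms4a4c and 0.0228% of Synj2. That share argues against exact copies for Synj2 and leaves them open for the other 7. Copies that differ by single bases, or that lie outside annotated transcripts, were not searched. Reads shared with such near-identical copies stay open for every gene of the set. Strain or donor variants outside Morrbid may fit but were not settled. Of these genes 2 pairs, Erdr1 with Mid1 and Synj2 with Tmem181b-ps, lay within 1 Mb of each other (permutation p = 0.0055 over 10000 random sets). That count was chosen after the genes were seen, so the p-value describes the pairs and does not test the explanation. Erdr1 and Mid1 also held shared stretches, and Tmem181b-ps had no transcript to search. Variants at the loci of these pairs were not analysed here.

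Single libraries stood apart from the other 3 of their group in 8 of 100 groups of 4 examined over 50 named genes, where chance gives about 1 in 20. With IFN-beta, replicate 3 labelled Morrbid-/- held 519 counts of Slc20a1 (others 573 to 577), 325 of Ide (others 267 to 276), 73.7 of Ppic (others 104 to 110) and 68.3 of Cxcr6 (others 81.6 to 84.3). Replicate 2 with that label held 16780 counts of Gbp4 (others 15420 to 15560). Wild-type replicate 2 held 412 counts of Zc3h6 (others 367 to 373) and 88.1 of Lars2 (others 107 to 111), and wild-type replicate 1 held 46 of Rhob (others 28 to 29.7).

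Named genes whose genotype effect differed between stimulations, by the limma interaction contrast, numbered 19. Gbp7, Akap2, Bcl9l, B4galnt1, Kdm2b and Chd4 were named only for a small p in this contrast, so their place here was set by that rule. Gbp2, Iigp1, Gbp6 and Igtp met that rule as well. Among interferon-response genes the values were -2.18 for Gbp2 (adjusted p = 1.79e-11), -1.97 for Iigp1 (9.27e-11), -1.83 for Gbp6 (4.45e-09), -1.6 for Gbp5 (4.5e-05), -1.73 for Ifit1 (3.4e-08), -1.27 for Gvin1 (4.84e-07), -1.4 for Igtp (5.69e-09), -1.54 for Tgtp1 (5.69e-09), -1.53 for Gbp4 (2.2e-08) and -1.47 for Gbp7 (3.81e-09). Pydc3 was at -1.52 (adjusted p = 1.52e-08), Cxcr6 at -1.01 (0.0282) and Erdr1, near its floor with IFN-beta, at -3.41 (8.88e-05). The positive values were 0.87 for Akap2 (adjusted p = 1.62e-04), 1.03 for Bcl9l (2.75e-04), 0.63 for B4galnt1 (3.75e-04), 0.71 for Kdm2b (6.11e-04) and 0.61 for Chd4 (7.61e-04).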

How the results depend on the processing

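The alternatives of the 16S rRNA share as a covariate, of removing a GC and length trend and of thinning reads were chosen after results were seen, and the other alternatives before. No named gene turned direction under a setting in which it passed, or where it passed at first.

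Without IFN-beta the 50 higher and 9 lower genes became 13 and 4 without limma's trend, 94 and 75 with the replicate number as a block and 101 and 16 in one fit of all 14 libraries. The lower genes numbered 5 with a mean of at least 50 and 32 with the 16S rRNA share as a covariate. Leaving out 1 library gave 31 (without Morrbid-/- replicate 2) to 52 higher genes (without wild-type replicate 1) and 6 (without wild-type replicate 2) to 23 lower genes (without Morrbid-/- replicate 1). The block made the log2 change of Bcl2l11, -0.362 in both, pass (adjusted p = 0.0123), and the 16S rRNA share as a covariate did so at -0.375 (adjusted p = 0.0494). Deviations of libraries from their group mean were correlated across genes between the genotypes at equal replicate numbers. The correlations were 0.204, -0.0214 and 0.153 without IFN-beta and 0.0407, 0.0033, 0.0607 and 0.141 with it. Wild-type replicates 1 and 3 without IFN-beta, and 1, 3 and 4 with it, correlated best with the Morrbid-/- replicate of the same number. Pairing by number was thus left open, and the fit without the block, fixed beforehand, was kept.

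With IFN-beta the 523 higher and 482 lower genes became 171 and 134 without the trend and 301 and 253 in one fit of all 14 libraries. Leaving out 1 library gave 321 and 288 (without Morrbid-/- replicate 2) to 555 and 466 (without wild-type replicate 4). For the difference between stimulations, 40 higher and 81 lower genes became 15 and 51 without the trend and 148 and 163 with the block. The higher genes numbered 24 without wild-type replicate 1 with IFN-beta and 47 without Morrbid-/- replicate 1 without it.

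Of the lists called without IFN-beta, 10 by camera with the preset correlation, 0 passed with an estimated correlation. By fry 4 lists passed, 3 of them among these 10 and the other the memory-phenotype markers (adjusted p = 0.0426), and the type I interferon response had an adjusted p of 0.0619 with an estimated correlation. With IFN-beta 2 lists became 1 with an estimated correlation and 4 by fry, and 1 without Morrbid-/- replicate 1 to 5 without wild-type replicate 3. For the difference between stimulations 4 lists became 1 with an estimated correlation, 2 by fry and 2 with a mean of at least 50.

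Morrbid and Bcl2l11 aside, without IFN-beta 13 of 24 named genes, with it 23 of 29 and for the difference 10 of 10 kept their call and direction under every setting. The last 10 had been chosen for the smallest p of that contrast. Without the trend Gbp5 (adjusted p = 0.18), Ifit1 and Gbp4 (each 0.0712), Lars2 (0.217), Ccr9 (0.524) and Yae1d1 (0.106) did not pass. Ccr9 and Yae1d1, in the comparison without IFN-beta, also did not pass with reads thinned to the shallowest library (adjusted p = 0.0639 and 0.162), and Yae1d1 did not under DESeq2 (0.13) or total rescaling (0.0633). With IFN-beta Tmem87b did not pass without the trend (adjusted p = 0.115), under total rescaling (0.0914), in one fit of all 14 libraries (0.0647), with the 16S rRNA share (0.0689), with the GC and length trend removed (0.0585) or with reads thinned (0.0588).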

Other observations

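The tests over other splits of the libraries and the camera tests of the gene lists were set beforehand, and the tests on ND3, Nnt and ribosomal protein genes and the marker sums were chosen after results had been seen. With IFN-beta, the immunoglobulin genes Ighm and Ighd were lower in the libraries labelled Morrbid-/-, although the B-cell list did not pass. Ighm fell from 509 to 373 (-0.45, limma adjusted p = 3.24e-04) and Ighd by 0.83 (adjusted p = 0.0418). They were the 2 lower genes of 5 tested B-cell markers, 0 being higher, also over the list alone (camera adjusted p = 0.888, with a downward direction against a median of 0.51). Monocyte and macrophage markers had 0 higher and 0 lower of 6 (camera adjusted p = 0.966), with Cd68 at 0.62. Dendritic-cell markers, 3 tested with a median of 0.69 and 1 higher, Zbtb46, summed to 108 ± 15.9 in wild type and 140 ± 16.8 in the libraries labelled Morrbid-/-, and NK-cell markers to 1773 ± 107 and 2019 ± 217 (SD, n = 4 each). Markers of CD4 and regulatory T cells had 2 higher, Ctla4 and Ikzf2 (0.28, adjusted p = 0.0164), and 1 lower, Tnfsf8 (-0.58, adjusted p = 1.39e-06), of 6 (3 and 1 over the list alone; camera adjusted p = 0.7).

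Marker sums of other cell types went both ways between genotypes without IFN-beta (SD, n = 3 each). Markers of CD4 and regulatory T cells summed to 1171 ± 121 in wild type and 1321 ± 92.8 in the libraries labelled Morrbid-/-, and memory-phenotype CD8 markers to 5266 ± 532 and 4664 ± 50.8. B-cell markers summed to 327 ± 51 in wild type and 310 ± 24.1 in the libraries labelled Morrbid-/-, mostly from Ighm. Monocyte and macrophage markers summed to 369 ± 74.5 and 374 ± 38.8, mostly from Ctss, and neutrophil markers to 26.9 ± 4.12 and 32.5 ± 1.03. Dendritic-cell markers summed to 142 ± 37.1 and 105 ± 17.9, with Ccr9 lower, and NK-cell markers to 299 ± 7.74 and 325 ± 20.4, with Eomes higher and a median change of 0.38 (SE 0.58) over 2 tested markers. Erythroid markers summed to 26.6 ± 2.78 and 25.8 ± 9.16, and stromal and endothelial markers, mostly Pecam1, to 321 ± 22.2 and 310 ± 30.3.

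ND3, a mitochondrially encoded subunit of respiratory complex I, was at 4.47, 7.28 and 10.7 in wild type without IFN-beta and at 0, 2.62 and 1.02 in the libraries labelled Morrbid-/-. With IFN-beta it was at 27.1, 21.5, 22.2 and 20.5 against 0 reads in all 4. The other 10 mitochondrial transcripts tested there ran from -0.25 to 0.81. Nnt, a mitochondrial transhydrogenase gene, was at 42.5, 53.2, 40.9 and 27.3 in wild type with IFN-beta and at 78.8, 83.4, 81.8 and 78.5 in the libraries labelled Morrbid-/-. Without IFN-beta Nnt was at 38.4, 37.5 and 49.7 against 41.6, 45.8 and 66.5. Strain variants may change what the ND3 and Nnt values mean, and were not tested for these genes. Only the positions of the 12 genes changed the same way in both comparisons were examined, by a count chosen after those genes were seen.

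Ribosomal protein genes, 81 measured, had a median of -0.05 with IFN-beta, with 6 higher and 17 lower, and of 0.09, with 16 higher and 11 lower, once the 16S rRNA share was a covariate. Their direction there depended on that setting. Of the 10 splits of the libraries without IFN-beta into 3 and 3, 2 called at least as many genes as the genotype labels, the labels included. The labels called 59, the highest other split called 96, and 10 splits are too few to say more. That other split followed the 16S rRNA share, with 11 genes higher and 85 lower in the libraries of low share and 35 ribosomal protein genes among the lower, and it shared 1 gene with the genotype calls. Its fold changes had a Spearman rho of 0.451 with those of genotype across genes, which are not independent replicates, and 75 of the 81 ribosomal protein genes were negative between genotypes there. Both comparisons used the same libraries, with 2 wild-type libraries of high share and 2 Morrbid-/- libraries of low share. A positive correlation was therefore partly built in.

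With IFN-beta, 1 of 35 splits, the labels themselves, called as many as 1005 genes, and the highest other called 1, which argues against an arbitrary grouping. For the difference between stimulations, 1 of 100 regroupings, the labels themselves, called as many as 121 genes, and the highest other called 70. This argues against an arbitrary grouping as well. The regroupings also broke up the genotype effects within each stimulation, so they cannot show whether those effects differ between stimulations.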
